A study of Rattus norvegicus with 38 samples.

How the data were processed

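RNA from the left liver lobe of 38 untreated male F344 (Fischer) rats was measured on 2-colour Agilent rat oligonucleotide arrays read with Agilent's Feature Extraction software, per the labels and the series' design text. The rats were sentinels, animals kept alongside long toxicity studies to watch over the health of the colony, and the chemical in each label names only the study a rat belonged to. The ages were 6 months (15 rats, about 32 weeks old), 12 months (10 rats, about 58 weeks old) and 18 months (13 rats, about 84 weeks old). The 6-month rats came from the DMPT, pyrogallol and pulegone studies with 5 rats each. The 12-month rats came from the 1,2-dibromo-2,4-dicyanobutane and bis_2-chloroethoyl_methane studies with 5 each, and the 18-month rats from the beta-myrcene (5), 5-hydroxymethyl-2-furfural (5) and isoeugenol (3) studies. Per the labels, each rat was labelled with Cy5 and hybridised against a Cy3-labelled pool of RNA from 63 sentinels, 25 of them at the youngest age, 25 at the middle age and 13 at the oldest. The replicate numbers follow the order of the samples and pair nothing.

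The deposited values were standardized scores: each of the 38 columns had a mean near 0 (-0.00112 to 0.00122) and an SD near 1 (0.992 to 1.00) over its probes, as found from the values, and the normalization and standardization steps are not given in the sources used here. Column medians ran from -0.076 to 0.131 at 6 months, from -0.047 to 0.08 at 12 months and from -0.071 to 0.008 at 18 months. A positive score was read as more RNA in the rat than in the pool, from the dyes in the labels. Scale and centring before deposit stay unknown, and the direction was read from the labels, since the series' design text names both dyes without saying which sample took which. No scanner files were used here, so signal over background is unknown, and the number of arrays limits the precision.

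The scores of each array lay on an even grid, with all values within 0.00065 of it (100% of values on each array). Placing the spike of identical values at 0 and dividing by the grid step gave whole numbers of steps. Taking the step before standardization as 0.001 turned these into log ratios. The base of that logarithm is not stated. It was taken as log2 because the pool holds the same age groups as the rats. Over the 1% most variable probes (203), the mean log ratio fell with its variance with a slope of -0.311 (SE 0.0474), against -0.347 expected for log2, -0.5 for natural logarithms and -1.15 for log10. Over the 10% most variable (2027) the slope was -0.224 (SE 0.0184), and over all probes it was -0.123 (SE 0.00563). A log10 ratio kept to 4 decimals would give -0.115, nearer than log2 to the slopes of all probes and of the 10%, so the base is not settled, and on that reading sizes would be 0.332 times as large. As log2, 1 recovered value (6.58) exceeds the 5.98 that a transcript in 1 of the 63 pooled rats could reach. Sizes printed as log2 come from this recovered scale, and every call came from the scores. The tests had been planned for log2 ratios, and limma was applied in the planned form to the scores instead.

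The file held 20277 probes, of which all had values on at least 80% of the arrays of each age and were tested, and 10 lacked a value on some array. In the probe annotation, 12594 probes had 1 gene symbol, 5 had several and 7678 had none listed. Identifiers of 12565 probes matched the RefSeq gene table, which supplied current symbols, for 9651 genes. For the 2139 genes with more than 1 probe, the probe with the fewest missing values and then the largest SD over all arrays, regardless of age, stood for the gene, and probes that disagree are named in the text.

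Differences between ages were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided) on all 38 arrays, with age as a factor and study as a random block through duplicateCorrelation (correlation 0.425), since each study holds rats of 1 age. An adjusted p is limma's Benjamini-Hochberg value over all probes tested, with a threshold of 0.05. The same fit gave an F test over the 3 ages and a test of the 12-month mean against the line between the other ages. Study differences were tested with an F statistic over the 5 contrasts between studies of the same age. Gene lists (35, with 1317 listed symbols, of which 931 were measured) were tested with camera, which compares a list with all other genes, at a preset correlation between genes of 0.01. Camera with an estimated correlation and fry, which tests the members alone, were alternatives. The label fields gave 1 further split, the way titles write the age: the DMPT and pyrogallol arrays (10) use one style and the other 28 arrays another. The age comparisons were also made within those 28 arrays. Correlations across rats used permutation tests with 100000 resamples. Figures were drawn with matplotlib 3.10.9 (Python 3.11.15, numpy 2.4.6, pandas 2.3.3).

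Groups, tests, gene lists, most alternatives and the rule for named genes were fixed before the data were examined. The rule took, between 18 and 6 months, the 12 genes with the largest log2 rise and the 12 with the largest fall. A gene had to pass the threshold, and all study means of one age had to lie on one side of all study means of the other. The other pairs of ages took 5 and 5, the test against a line took up to 3 each way, and the study differences took the 5 largest F values. Each list gave its up to 4 members with the smallest p between 18 and 6 months. List members outside the rule are named where they passed or show the list's values, and they were chosen after their values were seen.

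Alternatives were: study ignored or study means as the unit; median centring, quantile normalization or equal median absolute deviation of the arrays; array weights; robust eBayes; probes with values on all 38 arrays or with the larger SDs; an adjusted p below 0.01 or a fold of at least 1.5; the mean of a gene's probes; and leaving out each study in turn. Chosen after seeing the data were 4 more: the recovered log ratios, the 28 arrays alone, title style as a second term, and the DMPT and pyrogallol arrays with their sign turned.

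The procedure was tested on simulated data of 20267 probes with study effects, independent between probes, and known changes of 1, 2 and 4 score units. These sizes were not scaled to the spread of each probe. Between 18 and 6 months it recovered 38.8%, 74.6% and 98.5% of the changed probes with 16 false calls. Between 12 and 6 months it recovered 28.4%, 70.1% and 90.9% (12 false calls), and between 18 and 12 months 19.4%, 65.7% and 89.4% (12 false calls). For departure from a line the shares were 34.3%, 79.1% and 97.0% (17 false calls), for the F test over ages 26.9%, 73.1% and 97.0% (21 false calls), and for study differences 35.8%, 73.1% and 87.9% (10 false calls). With no age effect, the study block gave 0 calls between 18 and 6 months where ignoring the study gave 1577. All 3 shifted lists were called, and 0 of the 32 others, in probes simulated as independent. On the real data, other assignments of the ages to rats called a median of 2 lists between 18 and 6 months and 3 in each other pair.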

Results

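Gene expression was compared between livers of untreated male F344 (Fischer) rats, an inbred strain, at 6 months (15 rats), 12 months (10 rats) and 18 months (13 rats). Each liver was measured against 1 pool of RNA from 63 such rats on its own array with 20277 probes, and the rats of each age came from 2 or 3 studies. Sizes below are differences in the recovered log ratio, taken as log2 although its base is not stated, with the standard error (SE) of the fit; read as log10 ratios kept to 4 decimals, they would be 0.332 times as large. Each adjusted p is limma's, computed on the deposited scores.

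The comparison of 18-month with 6-month livers asked which transcripts differ between aged and young adult rats. Sult1e1, an estrogen sulfotransferase, fell by 3.66 (SE 0.66, 13 against 15 rats, adjusted p 0.00241), and Cyp3a2, a male-specific steroid hydroxylase, fell by 3.54 (SE 0.88, adjusted p 0.0159). Stac3 fell by 3.05 (SE 0.44), Inmt, a methyltransferase, fell by 2.38 (SE 0.39), and Hao2, a peroxisomal hydroxyacid oxidase, fell by 2.16 (SE 0.27). The largest rise was that of Trim24, a transcriptional cofactor, by 2.22 (SE 0.35, adjusted p 0.000897), followed by the reticulon Rtn4 at 1.79 (SE 0.21, adjusted p 2.15e-05).

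Further falls were those of Cyp4a8 at -2.0 (SE 0.44), Marveld1 at -1.83 (SE 0.31), the cadherin Cdh17 at -1.82 (SE 0.49), the annexin Anxa6 at -1.80 (SE 0.35), and Ppp1r3b, a subunit that directs a phosphatase to glycogen, at -1.78 (SE 0.55). Chrnb2, a nicotinic receptor subunit, stood at -1.65 (SE 0.29), and Alas1, the first enzyme of heme synthesis, at -1.46 (SE 0.36). Rises were found for the protease Prss8 at 1.76 (SE 0.32), the phospholipase Pla1a at 1.70 (SE 0.22), the macrophage elastase Mmp12 at 1.69 (SE 0.35), and Aacs, which activates acetoacetate for lipid synthesis, at 1.66 (SE 0.35). Tsx rose by 1.64 (SE 0.40), the zinc finger gene Sall1 by 1.63 (SE 0.35), the fatty acid elongase Elovl6 by 1.54 (SE 0.47), and the tight junction gene Cldn7 by 1.54 (SE 0.31). Acsm2, an acyl-CoA synthetase, rose by 1.51 (SE 0.20), and Cd5, a surface protein of T cells, by 1.42 (SE 0.31). Adjusted p values of these 24 genes ran up to 0.0419. The rule that chose them required the 3 study means at 18 months to lie on one side of the 3 at 6 months. Mmp12 met it narrowly, with means of -1.24 in isoeugenol and -1.36 in pulegone in score units. The 3 other Sall1 probes stood at -0.01, 0.37 and -0.16 and did not pass, and a further Trim24 probe stood at 0.79 (adjusted p 0.138), whereas both other Inmt probes fell, to differences of -1.40 and -1.88.

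**Figure D1:**
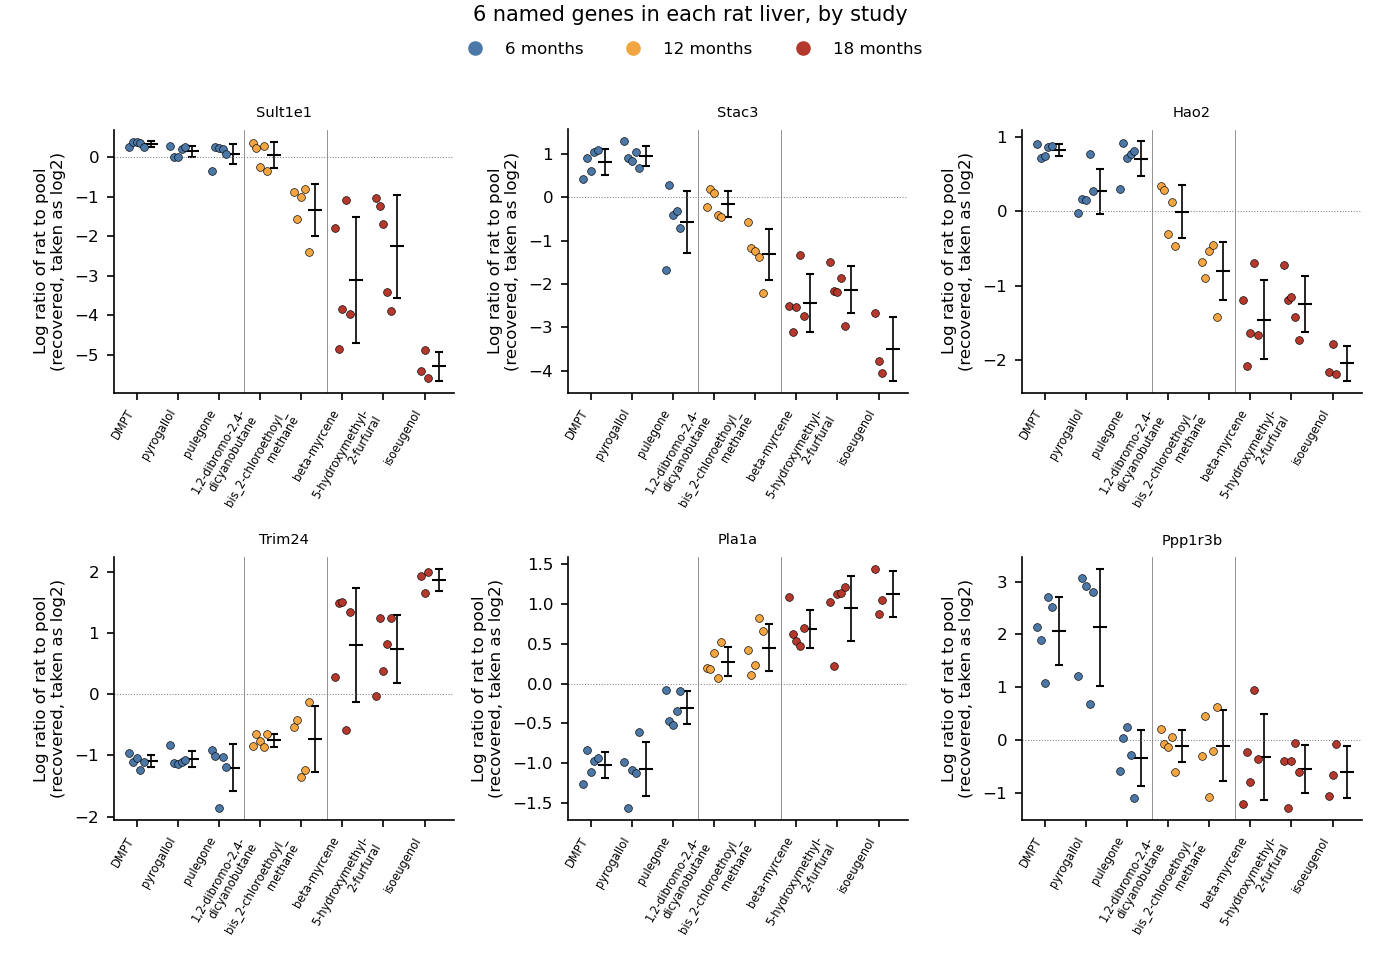
Log ratio of each rat to the pool (recovered scale, taken as log2; vertical axes differ between panels) for 6 genes in the 8 studies of the horizontal axis; each point is 1 rat, coloured by age, and each black bar is a study mean ± SD. Sult1e1 averaged 0.19 at 6 months and -3.28 at 18 months, while the Ppp1r3b means of the DMPT and pyrogallol studies lay above those of all other studies, with 1 pyrogallol rat (0.68) below 1 beta-myrcene rat (0.96), and the gene differed by -0.15 between the 18-month rats and the pulegone rats of 6 months.

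Differences between the 6-month studies entered these values unequally. Within the 28 arrays that share a title style, where the pulegone rats are the only 6-month rats, the 18-month rats differed from them by -3.51 for Sult1e1, -3.43 for Cyp3a2, -2.25 for Hao2, 2.28 for Trim24 and 1.20 for Pla1a. The same difference was -0.15 for Ppp1r3b, -0.20 for Alas1, 0.35 for Tsx and 0.40 for Cldn7. Of the 24 genes, 4 passed in those arrays: Pla1a, Hao2 and Marveld1 (adjusted p 0.0464 each) and Acsm2 (adjusted p 0.0487). Leaving out 1 study, 11 passed without DMPT (adjusted p up to 0.290), 11 without pyrogallol (up to 0.253), 14 without isoeugenol (up to 0.240), 18 without 5-hydroxymethyl-2-furfural (up to 0.141), 22 without beta-myrcene (up to 0.104) and 24 without each of the other 3.

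Genes expressed more in male than in female rat liver were called down as a list. Of 14 measured members, 9 fell and 1 rose, 4 did not pass, and the counts adjusted over the list alone were also 9 and 1. The falls included Stac3 and Cyp3a2, given above, the organic anion transporter Slc22a8 at -1.30 (SE 0.25), the testosterone hydroxylase Cyp2c11 at -1.38 (SE 0.33) and Cyp2a2 at -0.87 (SE 0.19), while Ces2c rose by 0.41 (SE 0.10). The list's mean difference was -0.98 and all 13 rats of 18 months lay below all 15 of 6 months (camera, adjusted p 0.00117; adjusted p = 0.348 with an estimated correlation). In score units the rat means differed by -3.10 on all arrays. Within the 28 arrays the list's mean difference was -3.06 (camera, adjusted p 1.01e-08), and the hepatocyte list differed by 0.20 there. By the spread between the 18-month studies the pulegone mean lay 2.33 SE off (t test on study means, p 0.146). The call was lost without pulegone (camera, adjusted p 0.0538), where the rat means still differed by -3.17 in score units.

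Female-biased genes went both ways. Of 16 measured, 4 rose (Acsm2, Trim24, the prolactin receptor Prlr at 0.81, SE 0.20, and the female-specific Cyp2c12 at 1.26, SE 0.34). The 3 that fell were Hao2, Fmo1 at -0.76 (SE 0.19) and Cyp3a9 at -1.12 (SE 0.31), and 9 did not pass. Adjusted over the list alone, 7 rose and 4 fell, and the list was not called (adjusted p 0.514; 0.0210 within the 28 arrays). In the growth hormone and IGF list of 17 genes, 4 fell and 13 did not pass. Those were Cish, a suppressor of cytokine signalling induced by growth hormone, at -0.93 (SE 0.11), Igfbp3 at -0.54 (SE 0.14), Igf1 at -0.48 (SE 0.14) and Socs3 at -0.34 (SE 0.12). Adjusted over the list alone, 5 fell and 1 rose. The list was called down with a mean of -0.20 (camera, adjusted p 0.0230, and adjusted p = 0.348 with an estimated correlation), but not within the 28 arrays (adjusted p 0.279) or without pulegone (adjusted p 0.0517). In score units it averaged 0.0966 at 6 months, -0.450 in the pulegone rats among them and -0.552 at 18 months. The fall was thus small within the 28 arrays and larger without pulegone.

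Cholesterol synthesis genes were called up as a list. Of 20 measured, 9 rose, 0 fell at limma's threshold and 11 did not pass, and 10 rose adjusted over the list alone. Squalene epoxidase, Sqle, rose by 1.20 (SE 0.25), Cyp51 by 0.88 (SE 0.17), Acat2 by 0.83 (SE 0.18) and Fdft1 by 0.46 (SE 0.11). The list's mean was 0.48 (camera, adjusted p 7.28e-06; adjusted p = 0.348 with an estimated correlation), and 12 of 13 rats of 18 months lay above all 6-month rats. In score units the list averaged -0.599 at 6 months and 0.730 at 18 months, and its mean difference within the 28 arrays was 1.38 (camera, adjusted p 7.25e-15). That p does not measure the spread between studies. By the spread between the 18-month studies the pulegone mean lay 4.23 SE off (t test on study means, p 0.0516).

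Camera called 3 lists of immune genes up. Among 27 macrophage and Kupffer cell genes, 6 rose and 21 did not pass (8 rose adjusted over the list alone), led by Gpnmb at 1.17 (SE 0.20), Trem2 at 0.65 (SE 0.11) and Lgals3 at 0.51 (SE 0.11). Their mean was 0.30 (camera, adjusted p 0.000772, and adjusted p = 0.348 with an estimated correlation). In score units the list averaged -0.714 at 6 months and 0.0879 at 18 months, and its mean difference within the 28 arrays was 0.51 (camera, adjusted p 9.77e-05). Of 28 genes of MHC class I and the interferon response, 7 rose and 21 did not pass, with 9 higher and 2 lower adjusted over the list alone. Ubd, a ubiquitin-like modifier, rose by 1.34 (SE 0.23) and the GTPase Irgm by 0.51 (SE 0.12). That list's mean was 0.23 (camera, adjusted p 0.0136; adjusted p = 0.348 with an estimated correlation; within the 28 arrays adjusted p 8.17e-06). Of 33 T and NK lymphocyte genes, 6 rose and 27 did not pass, and 6 rose adjusted over the list alone. They included Cd5, given above, Cd3g at 0.93 (SE 0.16), Ptprc at 0.72 (SE 0.16) and Rac2 at 0.55 (SE 0.13). The mean was 0.23 (camera, adjusted p 0.0230, and adjusted p = 0.390 with an estimated correlation), with 9 of 13 rats of 18 months above all 6-month rats. In score units it was 0.62 on all arrays and 0.39 within the 28 arrays (camera, adjusted p 0.00277). Camera's p values within the 28 arrays do not measure the spread between studies. By the spread between the 18-month studies the pulegone means of the macrophage, MHC class I and lymphocyte lists lay 2.73, 3.69 and 2.58 SE off. The t test on study means gave p 0.112, 0.0663 and 0.123 for them. Without pulegone the MHC class I and lymphocyte lists lost the call (camera, adjusted p 0.114 each), though their rises were not smaller. In score units the pulegone means (-0.411 and 0.0229) lay above the means of all 6-month rats (-0.557 and -0.203). Of 12 genes of MHC class II antigen presentation, Lgmn at 0.48 (SE 0.12) and Cd83 at 0.55 (SE 0.17) rose, Ciita at -0.30 (SE 0.08) and RT1-DMa at -0.25 (SE 0.10) fell and 8 did not pass, with 2 and 2 adjusted over the list alone (camera adjusted p 0.910, 0.880 within the 28 arrays). Of 18 neutrophil and inflammatory cytokine genes Cxcl1 rose by 0.88 (SE 0.27) and 17 did not pass, with 0 adjusted over the list alone (camera adjusted p 0.514, 0.694 within the 28 arrays).

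The other 4 called lists were 3 of metabolic and hepatocyte genes, called down, and the ribosomal proteins, called up. Of 37 cytochrome P450 and other phase I genes, 12 fell, 2 rose and 23 did not pass (16 and 5 adjusted over the list alone). Ces1e fell by 0.75 (SE 0.19) and Cyp3a23-3a1 by 1.30 (SE 0.26), while the retinoic acid hydroxylase Cyp26a1 rose by 0.91 (SE 0.22). The list's mean was -0.28 (camera, adjusted p 0.0322; adjusted p = 0.348 with an estimated correlation), and it was not called within the 28 arrays (adjusted p 0.353). Of 35 amino acid and urea cycle enzymes 4 fell and 31 did not pass, also 4 adjusted over the list alone, with Got2 at -0.43 (SE 0.13) and Ahcy at -0.38 (SE 0.12). The mean was -0.17 (camera, adjusted p 0.0136; adjusted p = 0.758 with an estimated correlation; 0.347 within the 28 arrays). Of 31 hepatocyte secreted and identity genes 5 fell and 26 did not pass, and 6 fell adjusted over the list alone, among them Apob at -1.06 (SE 0.31) and Lipc at -0.68 (SE 0.22). Their mean was -0.23 (camera, adjusted p 0.0136, and adjusted p = 0.758 with an estimated correlation). In score units the rat means differed by -0.76 on all arrays, but the list's mean difference within the 28 arrays was 0.20 (camera, adjusted p 0.449). Of 48 ribosomal protein genes 8 rose, 3 fell and 37 did not pass (9 and 4 adjusted over the list alone), with Rpl32 at 0.42 (SE 0.10) and Rps7 at 0.54 (SE 0.15). That list was called up with a mean of 0.08 (camera, adjusted p 0.0282; adjusted p = 0.758 with an estimated correlation; 0.0147 within the 28 arrays). Leaving out 1 study ended the call of the P450 list without pulegone (adjusted p 0.0538), pyrogallol (0.0711) or bis_2-chloroethoyl_methane (0.0523), of the ribosomal list without pulegone (0.154) or isoeugenol (0.168), and of the amino acid list without isoeugenol (0.0632).

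**Figure D2:**
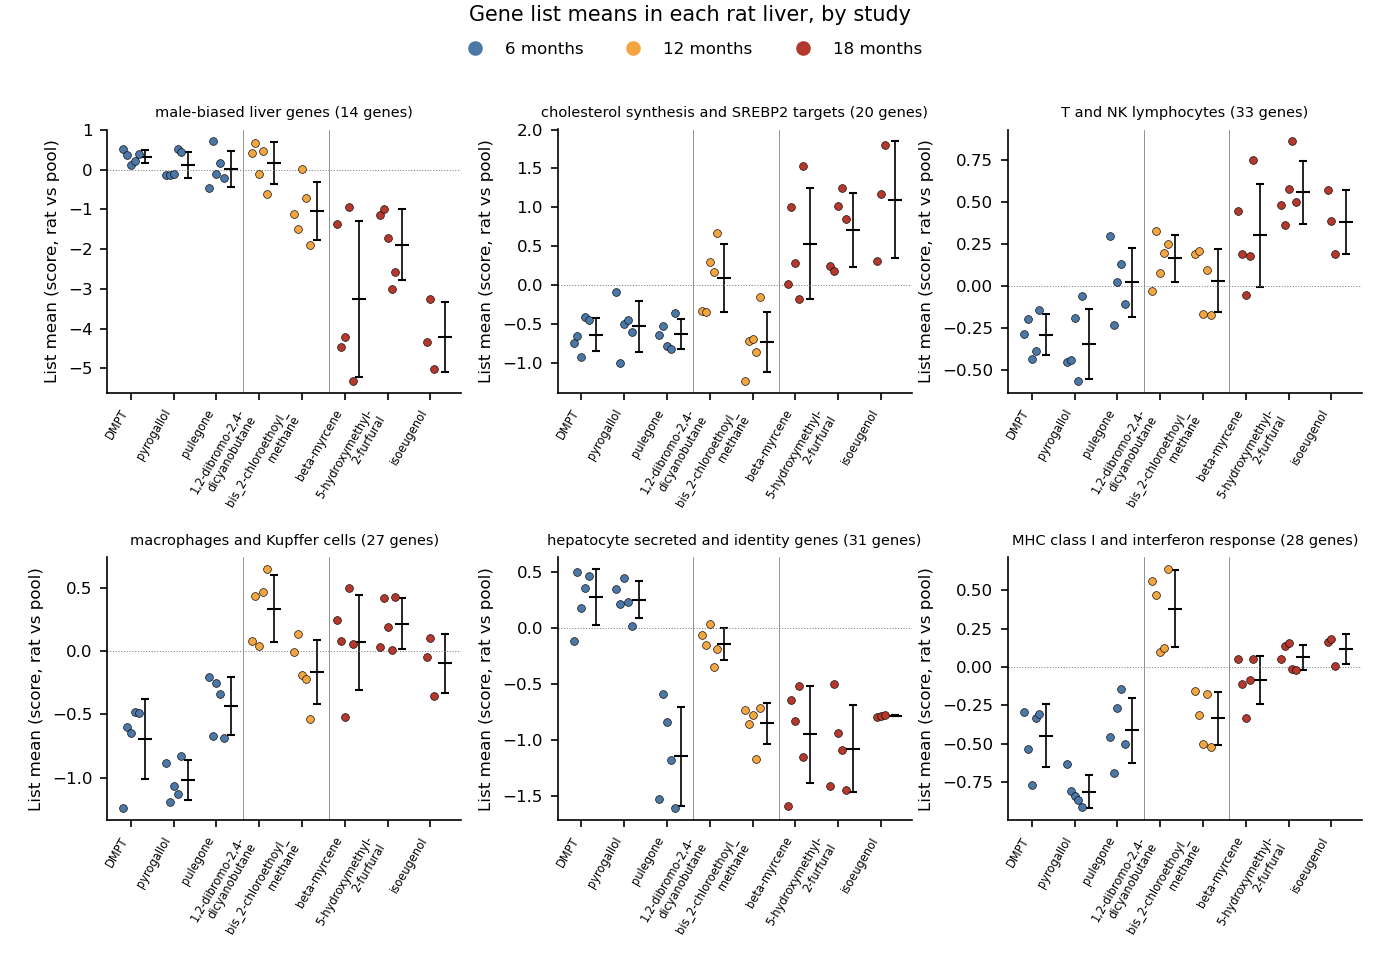
Mean score of each rat against the pool over the measured genes of 6 lists (vertical axes differ between panels) for the 8 studies of the horizontal axis; each point is 1 rat, coloured by age, and each black bar is a study mean ± SD. Male-biased genes averaged 0.153 at 6 months and -2.95 at 18 months, whereas hepatocyte genes averaged -1.15 in the pulegone study of 6 months and between -1.08 and -0.787 in the 18-month studies.

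Over all probes, 2738 of 20277 (13.5%) differed between 18 and 6 months, 1481 higher and 1257 lower (1768 and 975 with each array centred on its median). Study means of the ages did not overlap for 24.4% of probes, against 10% if the studies were exchangeable. They were not: DMPT and pyrogallol correlated at 0.674 with each other and at -0.251 to -0.486 with pulegone and the 18-month studies. The excess over 10% therefore does not by itself show a difference with age. The count depended on the studies: it was 115 without the DMPT study, 108 without pyrogallol, 8971 without pulegone, 4634 without 1,2-dibromo-2,4-dicyanobutane, 4698 without bis_2-chloroethoyl_methane, 945 without beta-myrcene, 492 without 5-hydroxymethyl-2-furfural and 342 without isoeugenol. It was 9027 with the study ignored, 0 with study means as the unit (limma; 3254 at an unadjusted p below 0.05), 8 within the 28 arrays of one title style and 18 with the DMPT and pyrogallol arrays turned in sign.

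Livers of 12 and 6 months were compared to see which transcripts differ by middle age. Mmp12 rose by 1.69 (SE 0.38, 10 against 15 rats, adjusted p 0.0360) and Gpnmb, a glycoprotein of lipid-laden macrophages, by 1.05 (SE 0.22, adjusted p 0.0334). The phosphatase gene Ppp4c rose by 1.18 (SE 0.22), Pla1a by 1.16 (SE 0.24) and Stt3a, a subunit of the glycosylation complex, by 1.15 (SE 0.23). Nrep fell by 1.58 (SE 0.32), the nucleolar GTPase Gnl3 by 1.10 (SE 0.21), Parp2 by 1.00 (SE 0.21), the ribosomal protein gene Rpl39 by 0.98 (SE 0.15, adjusted p 0.00163) and the transcriptional cofactor Cited2 by 0.94 (SE 0.21). The second probes of Stt3a and Parp2 did not pass (adjusted p 0.891 and 0.648). Within the 28 arrays the adjusted p of these 10 genes ran from 0.351 to 0.926, without DMPT from 0.0857 to 0.646 and without pyrogallol from 0.0729 to 0.581. Of the 10, 2 passed without beta-myrcene (adjusted p up to 0.134), 4 without 5-hydroxymethyl-2-furfural (up to 0.101), 6 without 1,2-dibromo-2,4-dicyanobutane (up to 0.257) and 7 without isoeugenol (up to 0.0736).

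Among lists, macrophage genes were called up between 12 and 6 months with a mean of 0.27. Of 27 members Gpnmb alone passed and 26 did not, and 6 rose adjusted over the list alone; Trem2 stood at 0.52 (SE 0.13, adjusted p 0.0570) and Lgals3 at 0.50 (SE 0.12). Camera gave an adjusted p of 8.52e-06 (adjusted p = 0.281 with an estimated correlation), and 8 of 10 rats of 12 months lay above all 6-month rats. In the heat shock and unfolded protein list of 34 genes, the chaperones Hspa9 at 0.54 (SE 0.12) and Dnajb9 at 0.83 (SE 0.20) rose and 32 did not pass (9 higher, 1 lower adjusted over the list alone). Its mean was 0.17 (camera, adjusted p 0.00200; adjusted p = 0.281 with an estimated correlation). Of 28 MHC class I and interferon genes 0 passed in limma and 3 rose adjusted over the list alone, with Ubd at 1.04 (SE 0.25, adjusted p 0.0567); the mean was 0.19 (camera, adjusted p 0.0111; adjusted p = 0.281 with an estimated correlation). Of 18 acute phase genes, the copper carrier Cp rose by 0.84 (SE 0.16), 17 did not pass and 5 rose adjusted over the list alone, with a mean of 0.21 (camera, adjusted p 0.0119; adjusted p = 0.378 with an estimated correlation). Of 26 complement and coagulation genes 0 passed in limma and 8 rose adjusted over the list alone, with C6 at 0.69 (SE 0.23) and Cfi at 0.46 (SE 0.12), and the mean was 0.12 (camera, adjusted p 0.0276; adjusted p = 0.684 with an estimated correlation). Oxidative phosphorylation genes were called down with a mean of -0.12. Of 50 members Atp5pf at -0.54 (SE 0.09), Cox8a at -0.50 (SE 0.11) and Ndufa5 at -0.47 (SE 0.10) fell and 47 did not pass, with 6 lower adjusted over the list alone (camera, adjusted p 0.00263; adjusted p = 0.718 with an estimated correlation). Within the 28 arrays, 5 of these 6 lists passed and the heat shock list did not (adjusted p 0.0884). Without 1,2-dibromo-2,4-dicyanobutane the call was lost by the heat shock (adjusted p 0.688), MHC class I (0.417), acute phase (0.417) and complement lists (0.444). Mean scores of the heat shock list were 0.650 in that study and -0.471 in bis_2-chloroethoyl_methane, against -0.335, -0.696 and -0.301 in DMPT, pyrogallol and pulegone. Without pulegone it was lost by the MHC class I (0.131), acute phase (0.595), complement (0.676) and oxidative phosphorylation lists (0.131), the last of which also lost it without bis_2-chloroethoyl_methane (0.763).

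Between 12 and 6 months 59 probes differed, 37 higher and 22 lower. Study means did not overlap for 13.2% of probes, against 20% if the studies were exchangeable, which they were not. The count was 2 without the DMPT study, 2 without pyrogallol, 5111 without pulegone, 194 without 1,2-dibromo-2,4-dicyanobutane, 2338 without bis_2-chloroethoyl_methane, 13 without beta-myrcene, 22 without 5-hydroxymethyl-2-furfural and 27 without isoeugenol. It was 0 within the 28 arrays (limma; 1534 at an unadjusted p below 0.05), 0 with study means as the unit (1183 at an unadjusted p below 0.05), 3312 with the study ignored and 4 with the DMPT and pyrogallol arrays turned in sign.

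The comparison of 18 with 12 months asked what differs late in life. Lists were called although 0 probes passed in limma (1199 at an unadjusted p below 0.05; 1550 passed with the study ignored and 0 with study means as the unit, where 1057 had an unadjusted p below 0.05). Cholesterol synthesis genes were called up with a mean of 0.36: 0 of 20 passed and 10 rose adjusted over the list alone, with Sqle at 1.15 (SE 0.28, 13 against 10 rats) and Idi1 at 0.82 (SE 0.21). Ribosomal protein genes were called up with a mean of 0.18: 0 of 48 passed and 5 rose adjusted over the list alone, with Rpl39 at 0.55 (SE 0.15) and Rps24 at 0.30 (SE 0.09). T and NK lymphocyte genes were called up with a mean of 0.13, with 0 of 33 passing either way. Male-biased genes were called down with a mean of -0.80: 0 of 14 passed and 8 fell adjusted over the list alone, with Stac3 at -1.92 (SE 0.49) and Cyp3a2 at -3.05 (SE 0.98). Camera gave adjusted p values of 1.01e-09, 1.20e-11, 0.0129 and 6.37e-07 for these 4 lists, and with an estimated correlation adjusted p = 0.173, 0.173, 0.322 and 0.173. The lymphocyte list lost the call without 1,2-dibromo-2,4-dicyanobutane (adjusted p 0.292), bis_2-chloroethoyl_methane (0.0740) or 5-hydroxymethyl-2-furfural (0.0761), the male-biased list without 1,2-dibromo-2,4-dicyanobutane (0.0635) and the ribosomal list without bis_2-chloroethoyl_methane (0.0572).

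Also called down between 18 and 12 months were 5 metabolic and stress lists, in none of which a member passed in limma. Of 35 amino acid and urea cycle enzymes (mean -0.20) 0 fell adjusted over the list alone, with Gpt at -0.50 (SE 0.20) and Ass1, an enzyme of the urea cycle, at -0.62 (SE 0.31). Of 30 fatty acid oxidation genes (mean -0.12) 0 fell adjusted over the list alone, with Acox2 at -0.46 (SE 0.16) and Cpt1a at -0.49 (SE 0.26). The same count was 0 for 31 hepatocyte genes (mean -0.14) and for 23 bile acid genes (mean -0.14, with Cyp7b1 at -0.93, SE 0.49), and 1 for 28 immediate early genes (mean -0.17, with Per1 at -0.94, SE 0.28). Camera gave adjusted p values of 2.14e-07, 0.00327, 0.00978, 0.0107 and 0.0107 in this order, and with an estimated correlation adjusted p = 0.201, 0.533, 0.533, 0.173 and 0.201. Leaving out 1,2-dibromo-2,4-dicyanobutane raised the count of probes from 0 to 302 and lowered that of lists from 9 to 5, with 3 of the 9 among them. Lost were the amino acid (adjusted p 0.205), bile acid (0.314) and hepatocyte lists (0.966) as well as the 2 given above, and the fatty acid oxidation list reversed (0.966; mean scores 0.362 in that study and -0.468 in bis_2-chloroethoyl_methane). Without bis_2-chloroethoyl_methane the bile acid (0.0531) and immediate early lists (0.374) were lost. The probe count was 222 without bis_2-chloroethoyl_methane and 176 without pulegone. All 9 lists passed within the 28 arrays, where 6 probes did, and 1 probe passed with the DMPT and pyrogallol arrays turned in sign.

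Over the 3 ages together 1286 probes changed by the F test. Rpl39 was the 1 probe off a straight line with age (698 at an unadjusted p below 0.05): at 12 months it lay 0.77 below the line between the other ages (-0.77, SE 0.13, adjusted p 0.0487). Its study means at 12 months, -1.73 and -0.914 in score units, lay below those of all other studies, of which the lowest was -0.0713. The adjusted p rose above 0.05 without DMPT (0.427), pyrogallol (0.319), 1,2-dibromo-2,4-dicyanobutane (0.0534), beta-myrcene (0.602), 5-hydroxymethyl-2-furfural (0.756) or isoeugenol (0.0812). Over all alternatives it ran from 9.19e-07 to 1.00, and it was 0.0947 within the 28 arrays.

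Rats of the same age but different studies also differed. The largest F values were those of the ribosomal protein gene Rps3 (69.8), Aldh6a1, an enzyme of valine breakdown (67.1), Sec62, a part of the protein import channel (65.5), Selenot (60.9) and Capza2 (60.5). Aldh6a1 averaged -1.76 in the DMPT, -1.69 in the pyrogallol and 0.406 in the pulegone rats in score units, and 2.19 and -1.04 in the studies of 12 months. Rps3 averaged -1.07, -1.39 and -0.0880 in the same 6-month studies. The further Selenot probe had not passed between 18 and 6 months (adjusted p 0.0971, against 0.00612).

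In all, 12675 probes (62.5%) differed between studies of an age: 10763 between the 6-month, 8892 between the 12-month and 39 between the 18-month studies. The count was 6882 within the 28 arrays. Over all probes the mean of the pulegone rats correlated with that of DMPT at r = -0.251 and of pyrogallol at r = -0.289, but with the 18-month studies at 0.637 (beta-myrcene), 0.713 (5-hydroxymethyl-2-furfural) and 0.616 (isoeugenol). These are correlations across probes, which are not independent replicates. Of 703 pairs of arrays, 64 correlated below -0.3, with a minimum of -0.480. Each comparison is for this reason also given with the sign of the DMPT and pyrogallol arrays turned. The pool-weighted mean ratio had a median absolute log2 of 0.16 as labelled and 0.29 with those arrays turned.

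**Figure D3:**
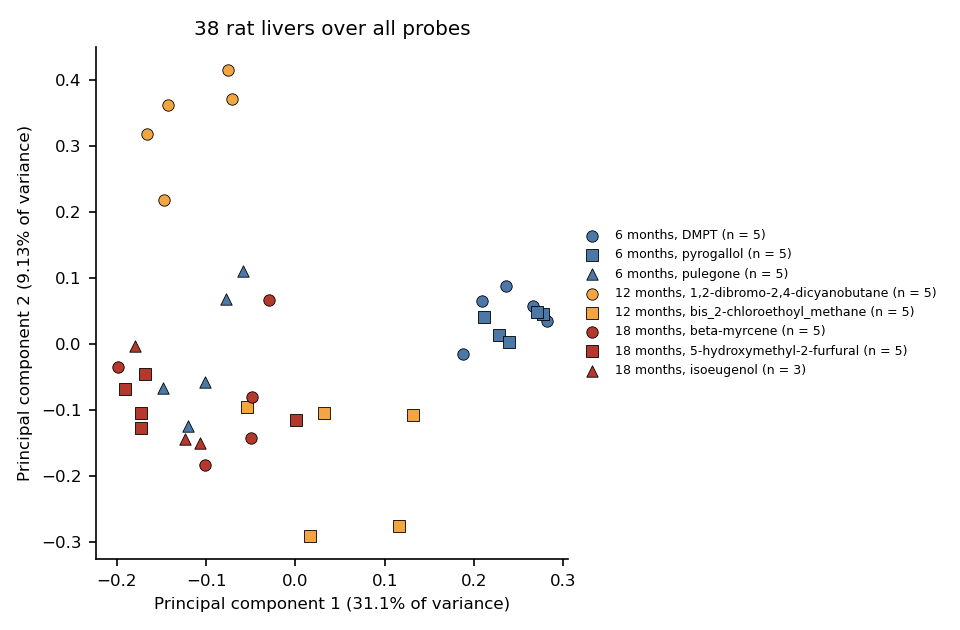
Position of the 38 rats on the first 2 principal components over all probes (axes in arbitrary score units with the percent of variance); each point is 1 rat, with colour for age and a marker for each study of an age. Component 1, with 31.1% of the variance, separated the DMPT and pyrogallol rats from the 28 rats of the other 6 studies, and component 2 held 9.13%.

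Markers of the cell types a piece of liver can hold were read in each rat, in score units. T and NK lymphocyte markers averaged -0.203 ± 0.238 at 6 months (SD, n = 15), 0.0980 ± 0.172 at 12 months (n = 10) and 0.419 ± 0.252 at 18 months (n = 13). The extremes were replicates 11 (0.296) and 9 (-0.565) at 6 months, 2 (0.329) and 10 (-0.171) at 12 months, and 9 (0.862) and 3 (-0.0560) at 18 months. Macrophage markers averaged -0.714 ± 0.335, 0.0853 ± 0.357 and 0.0879 ± 0.292 at the 3 ages. Their extremes were replicates 11 (-0.207) and 1 (-1.24) at 6 months, 5 (0.647) and 10 (-0.533) at 12 months, and 4 (0.497) and 3 (-0.520) at 18 months. B and plasma cell markers averaged -0.0616 ± 0.428, 0.138 ± 0.247 and 0.278 ± 0.459, with extremes at replicates 13 (0.443) and 6 (-1.01), 9 (0.503) and 3 (-0.207), and 10 (0.905) and 13 (-0.411). Bile duct markers averaged -0.482 ± 0.214, -0.0222 ± 0.202 and 0.00102 ± 0.241, with extremes at replicates 3 (-0.0850) and 14 (-0.752), 1 (0.335) and 7 (-0.386), and 7 (0.432) and 3 (-0.322).

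Stellate cell and matrix markers averaged -0.0840 ± 0.224, 0.0294 ± 0.165 and 0.0889 ± 0.135, with extremes at replicates 3 (0.333) and 9 (-0.413), 7 (0.314) and 1 (-0.324), and 10 (0.364) and 13 (-0.210). Endothelial markers averaged 0.0203 ± 0.196, 0.0553 ± 0.110 and -0.0518 ± 0.180, with extremes at replicates 10 (0.386) and 12 (-0.325), 7 (0.292) and 5 (-0.0854), and 4 (0.414) and 3 (-0.234). Erythroid markers averaged 0.162 ± 0.394, -0.128 ± 0.356 and -0.0899 ± 0.192, with extremes at replicates 3 (0.949) and 13 (-0.322), 7 (0.685) and 5 (-0.522), and 10 (0.264) and 12 (-0.428).

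Between 18 and 6 months camera called none of 6 further marker lists. Of 21 bile duct genes 6 rose, among them Cldn7, given above, the osteopontin gene Spp1 at 1.25 (SE 0.34) and Tspan8 at 1.10 (SE 0.24), 1 fell (the glucose transporter Slc5a1 at -0.34, SE 0.06) and 14 did not pass (6 and 3 adjusted over the list alone; camera adjusted p 0.629, 0.00499 within the 28 arrays). The list's mean was above 0 and its median below 0. Of 7 B and plasma cell genes Blnk rose by 0.41 (SE 0.09), Cd37 and Cxcr5 fell (-0.18, SE 0.05, and -0.19, SE 0.07) and 4 did not pass, with 2 and 2 adjusted over the list alone (camera adjusted p 0.910, 0.858 within the 28 arrays). Of 35 stellate cell and matrix genes the collagen Col3a1 fell by 0.29 (SE 0.08), the proteoglycan Bgn rose by 0.46 (SE 0.13) and 33 did not pass, with 1 and 1 adjusted over the list alone (camera adjusted p 0.812; called up within the 28 arrays, adjusted p 0.0263). Of 23 endothelial genes 2 rose and 3 fell, with Cdh5 at 0.62 (SE 0.15) and Rspo3, a Wnt agonist, at -0.89 (SE 0.23), and 18 did not pass (3 and 3 adjusted over the list alone; camera adjusted p 0.910, 0.872 within the 28 arrays). Of 15 erythroid genes 0 passed in limma, with Klf1 at -0.42 (SE 0.22), and 0 adjusted over the list alone (camera adjusted p 0.514, 0.872 within the 28 arrays). Of 21 genes of fat, pancreas and muscle, the lipoprotein lipase Lpl rose by 1.10 (SE 0.26), Reg1a fell by 0.25 (SE 0.09) and 19 did not pass, with 1 and 1 adjusted over the list alone (camera adjusted p 0.910, 0.797 within the 28 arrays); this list's mean was above 0, while its median and its test pointed down.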

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

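The tests of a wrong age label, of the male-biased and cholesterol genes and of the lymphocyte markers in this part were chosen only after the result was seen. Rpl39 is given for a closer look because its step from 6 to 12 months differed from its step from 12 to 18 months, by a test of departure from a straight line (-2.40 in score units, adjusted p 0.0487). The step from 6 to 12 months was -3.03 and that from 12 to 18 months 1.77. Among the 10 rats of 12 months, 0 of 35 list means and 0 of 37 named genes had a rat set apart by Dixon's test. These rats came from 2 studies that differed at 8892 probes, which widens the range the test divides by. A rat apart within its own study could thus be missed. The other ages have more than 10 rats and were not tested.

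Ages were dealt out anew to the rats in 100 ways, the real one included. Between 18 and 6 months 1 way gave as many probes as the real 2738 (highest other 3), between 12 and 6 months 2 ways as many as 59 (highest other 323), and over the 3 ages 1 way as many as 1286 (highest other 119). Such counts were thus rare when single rats were dealt out. The dealt ways mix ages within a study, whereas each real study holds 1 age, so they cannot exclude chance among studies. The 1 probe off a straight line was matched in 5 ways (highest other 94), so chance is not excluded there even among single rats. The 0 probes between 18 and 12 months (limma; 1199 at an unadjusted p below 0.05) could not be tested this way, since all 100 ways reach a count of 0 (highest other 1). As many lists as the 10 called between 18 and 6 months came in 2 ways (highest other 10), and as the 9 between 18 and 12 months in 2 ways (highest other 9), with the same limit. The 6 between 12 and 6 months were matched in 16 ways (highest other 10), so chance is not excluded for them even among single rats. The other ways called a median of 2, 3 and 3 lists in these comparisons. Shuffling rats between the studies of their age gave as many probes as the real 12675 in 1 of 100 ways (highest other 9273), so chance can be excluded there.

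Whole studies are the units that were assigned to ages, and each pair of ages has 10 groupings of them, too few for a share under 0.05. Between 18 and 6 months 2 groupings gave as many probes as the real 2738 (highest other 3141) and 5 as many lists as 10 (highest other 15). Between 12 and 6 months 4 gave as many probes as 59 (highest other 7206) and 5 as many lists as 6 (highest other 11), and between 18 and 12 months 2 gave as many lists as 9 (highest other 9), while for probes all 10 reach the real 0 (highest other 0), which tests nothing. Over the 3 ages, 11 of 100 drawn groupings gave as many probes as 1286 (highest other 8600), and off a straight line 12 of 100 as many as 1 (highest other 8716), so chance among whole studies cannot be excluded for these. Between 18 and 6 months the groupings with DMPT and pyrogallol on one side gave 3141 probes with beta-myrcene, 1134 with isoeugenol and 0 with 5-hydroxymethyl-2-furfural. Between 12 and 6 months they gave 7206 with bis_2-chloroethoyl_methane, 1610 with 1,2-dibromo-2,4-dicyanobutane and 6746 with the other 3 studies opposite them. Groupings that part DMPT from pyrogallol gave 0 probes in both comparisons (limma), so the large counts point to a structure of the samples along the title style, though not in each such grouping; within the 28 arrays of the other style 8 probes differed between 18 and 6 months and 0 between 12 and 6 months (limma; 861 and 1534 at an unadjusted p below 0.05).

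The DMPT and pyrogallol rats stood apart from the pulegone rats of the same age. Ratios turned over on the DMPT and pyrogallol arrays are argued against by the pool-weighted mean ratio, of which the log2 should lie near 0. Its median absolute log2 was 0.29 with those arrays turned (0.28 to 0.29 leaving out 1 array) and 0.16 as labelled (0.16 to 0.17). A batch of the DMPT and pyrogallol arrays as the whole cause of the changes between 6 and 18 months is argued against for the cholesterol genes, where 13 of 13 rats of 18 months lay above all pulegone rats, and for the male-biased genes below. A batch or other trait of the pulegone study itself is not excluded, since all its rats would share it. By the spread between the 18-month studies its mean lay off with p 0.0516 for cholesterol and 0.146 for male-biased genes (t test on study means). Over all probes a batch cannot be told apart from age and study, because title style and 6-month study coincide. There the difference from pulegone had a lowest median ratio to that from DMPT and pyrogallol of -0.0145, over probes picked by 5-hydroxymethyl-2-furfural. The other choices gave 0.0741 (beta-myrcene) and 0.0144 (isoeugenol), so such a batch may hold much of these changes, and a difference between the studies' rats stays open, untested. Pulegone rats of 18 months under a wrong label cannot be told apart either: 0 of the 5 lay inside the range of the 18-month rats in the male-biased genes, but their mean (0.0179) was only 2.33 SE from the 18-month studies by the spread between those (p 0.146), and of 35 lists 2 lay off with an unadjusted p below 0.05 (markers of altered foci by 15.2 SE, p 0.00430, and fatty acid synthesis by 4.57 SE, p 0.0447), about as many as chance gives, so 3 studies are too few to decide.

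Male-biased genes were lower at 18 months. The batch of the DMPT and pyrogallol arrays is argued against as the whole cause, since 13 of 13 rats of 18 months lay below all pulegone rats. A trait of the pulegone study itself is not excluded, because its mean lay only 2.33 SE from the 18-month studies (t test on study means, p 0.146). Fewer hepatocytes in the pieces are argued against as the whole cause, though not as a part of it: in score units the hepatocyte list stood at 0.186 and the male-biased list at -2.97 against pulegone, but at -1.23 and -3.17 against DMPT and pyrogallol, where they were still 1.94 apart (SE 0.487). A shift from the male to the female pattern stays open. On all arrays the female-biased list was not called (4 rose, 3 fell; camera, adjusted p 0.514). Still, 7 of 13 rats of 18 months lay above all 6-month rats in it. Within the arrays that share the title style of pulegone it was called up (camera, adjusted p 0.0210). By the spread between the 18-month studies, however, its pulegone mean lay only 1.30 SE off (t test on study means, p 0.323). The relation of the female-biased to the male-biased list did not pass the correction within studies. Over 13 rats r was -0.642 (permutation p 0.0183; rho -0.621, p 0.0261; r -0.719 without the 2 farthest rats; r -0.673 within studies, p 0.0429; adjusted p 0.0305 over 5 relations and 0.107 within studies). Age itself and the differences between studies stay open as well.

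T and NK lymphocyte markers were higher at 18 months. Lymphocytic leukaemia cells that set single rats apart are argued against as the source, since the largest of the upper gaps between neighbouring rats was 0.185 of their range. Such cells in more rats, or to a graded extent, would leave no gap and stay open. The genes of lymphocyte granules were not examined for this. Fewer hepatocytes, which would raise all other cell types alike, cannot be told apart: the list's difference between the ages exceeded that of erythroid markers by 0.890 (SE 0.217) and of endothelial markers by 0.691 (SE 0.269), but against the pulegone rats alone by 0.318 (SE 0.201) and 0.362 (SE 0.186), within 2 SE. More lymphocytes in the aged livers, or more of these transcripts in each cell, may remain as hypotheses; neither was tested.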

How the results depend on the processing

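The recovered ratios, the 28 arrays, title style as a term and the turned sign were chosen after the results were seen. Of 552 values of the 24 genes named between 18 and 6 months, 424 kept direction and side of the threshold, 124 lost the threshold and 4 turned; for the 10 genes between 12 and 6 months it was 141, 81 and 8 of 230, and for Rpl39 off a straight line 11, 12 and 0 of 23. Of the values of called lists, 155, 31 and 4 of 190 (18 and 6 months), 87, 21 and 6 of 114 (12 and 6) and 142, 28 and 1 of 171 (18 and 12) did so. Counts of probes follow in the order 18 and 6, 12 and 6, 18 and 12 months, off a straight line, and over the 3 ages, against 2738, 59, 0, 1 and 1286. They were 9027, 3312, 1550, 789 and 8992 with the study ignored, and 0, 0, 0, 0 and 0 with study means as the unit (limma; 3254, 1183, 1057, 798 and 1952 at an unadjusted p below 0.05). Array weights gave 10816, 4463, 168, 59 and 10064, the 28 arrays 8, 0, 6, 0 and 12, title style as a term 74, 0, 255, 85 and 185, and the turned sign 18, 4, 1, 3 and 14. Leaving out 1 study gave 108 to 8971, 2 to 5111, 0 to 302, 0 to 636 and 28 to 8243. An adjusted p below 0.01 left 663, 11, 0, 0 and 235, a fold of at least 1.5 left 737, 35 and, over the ages, 540, and the larger-SD probes 1818 between 18 and 6 months. Off a straight line equal median absolute deviation and robust eBayes left 0. Probes differing between studies numbered 6882 in the 28 arrays, where fewer studies were compared. Median centring, quantile normalization and recovered ratios moved no count by more than 1.5 times.

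Lists called, against 10, 6 and 9, were 0, 0 and 0 with an estimated correlation, 7, 3 and 0 with fry, 16, 14 and 9 in the 28 arrays, 17 and 14 (18 and 6, 12 and 6 months) with title style as a term, and 17 and 3 with the turned sign. Leaving out 1 study gave 4 to 11, 3 to 10 and 5 to 10. The hepatocyte list turned upward between 18 and 6 months in the 28 arrays (adjusted p 0.449) and with title style as a term (0.459), and the fatty acid oxidation list between 18 and 12 months without 1,2-dibromo-2,4-dicyanobutane (0.966; 2.78e-05 to 0.966 leaving out 1 study). With the turned sign the direction reversed between 18 and 6 months for Mmp12 (-1.33 in score units), Tsx (-0.688), Cldn7 (-0.158) and Ppp1r3b (2.73). Between 12 and 6 months it did for Mmp12 (-0.933), Ppp4c (-0.513), Pla1a (-0.344), Stt3a (-0.145), Gpnmb (-0.817), Gnl3 (0.734), Parp2 (0.810) and Cited2 (1.59). The lists it reversed were macrophages (adjusted p 0.0303) and MHC class I (0.410) between 18 and 6 months, and between 12 and 6 months macrophages (0.0454), MHC class I (0.223), acute phase (0.495), complement (0.282), heat shock (0.453) and oxidative phosphorylation (0.0454). The cause was not tested for any of these. Signal over background is unknown, so no limit from weak signal can be given.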

Other observations

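The tests of relations between lists in this part were chosen after the results were seen. Between 18 and 6 months further gene groups held members that changed without a call of their list by camera on all arrays. Fas, a death receptor, rose by 1.19 (SE 0.18), Ccng1 by 0.61 (SE 0.16) and Bax by 0.45 (SE 0.14) among 26 genes of p53, damage and senescence, Cdkn1b fell by 0.81 (SE 0.29), and 22 did not pass (3 and 1 adjusted over the list alone; adjusted p 0.910, and 0.0419 upward within the 28 arrays). Of 23 markers of altered hepatocyte foci 4 rose, with the placental glutathione transferase Gstp1 at 0.84 (SE 0.12) and Cd44 at 0.38 (SE 0.09), 4 fell, with H19 at -0.30 (SE 0.08), and 15 did not pass (4 and 4 adjusted over the list alone; adjusted p 0.667, and 0.0499 upward within the 28 arrays). Of 34 phase II genes 6 rose, with Gsta3 at 1.25 (SE 0.23) and Hmox1 at 0.54 (SE 0.12), 3 fell, with Sult1e1 and Gstm7 (-0.72, SE 0.16), and 25 did not pass (7 and 5 adjusted over the list alone; adjusted p 0.910, and 0.171 within the 28 arrays). Of 18 acute phase genes Lbp rose by 1.38 (SE 0.22), Cp by 0.82 (SE 0.14) and Kng2l1 by 0.40 (SE 0.09), and 15 did not pass (3 and 0 adjusted over the list alone; adjusted p 0.395, and 0.000471 upward within the 28 arrays). Of 27 lipogenic genes Elovl6, Scd2 (0.76, SE 0.15) and Cd36 (0.54, SE 0.12) rose, 2 fell and 22 did not pass (4 and 3 adjusted over the list alone; adjusted p 0.514, and 9.57e-06 within the 28 arrays).

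Cell cycle genes had a mean score of 0.567 (SD 0.10) in the 5 pulegone rats and between -0.209 and 0.197 in the other studies. Of 38 members Mcm4 (0.67, SE 0.19) and Cks2 (0.70, SE 0.22) rose between 18 and 6 months, Pttg1 (-0.33, SE 0.10) and Cdc20 (-0.31, SE 0.07) fell and 34 did not pass, with 2 and 2 adjusted over the list alone (adjusted p 0.484, and 4.41e-11 downward within the 28 arrays, where pulegone stands alone at 6 months). B and plasma cell markers averaged 0.758 (SD 0.102) in the 5-hydroxymethyl-2-furfural rats, 0.0933 (SD 0.292) in the beta-myrcene rats and -0.212 (SD 0.221) in the isoeugenol rats of 18 months; the difference between these studies was not tested for the list.

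It was asked as a hypothesis whether rats of 18 months with lower male-biased genes have higher cholesterol synthesis genes. Over 13 rats r was -0.669 (permutation p 0.0147; rho -0.764, p 0.00324; r -0.524 without the 2 farthest rats), with an adjusted p of 0.0305 over 5 relations, and -0.756 within studies (p 0.0124, adjusted p 0.0620). The relation may hold among these rats, but within studies it did not pass the correction. Each score had been divided by the SD of its own array, which ran from 0.247 to 0.421 at 18 months on the recovered scale. A shared divisor can by itself relate list means that lie far from 0. None of the 5 relations was computed on the recovered ratios, so that part was not separated. Of the other relations of the male-biased list, that with amino acid enzymes had r = 0.707 (permutation p 0.00840; rho 0.747, p 0.00468; 0.573 without the 2 farthest rats; adjusted p 0.0305; within studies 0.520, p 0.241). T and NK lymphocytes had r = 0.0425 (permutation p 0.890; rho -0.115, p 0.712; 0.413 without the 2 farthest rats; adjusted p 0.890), and the hepatocyte list r = -0.147 (permutation p 0.630; rho 0.00549, p 0.993; -0.451 without the 2 farthest rats; adjusted p 0.787).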
